A study of Mus musculus with 4 samples.

How the data were processed

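Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on forebrain of CD1 mouse embryos at embryonic day 11.5. CD1 is an outbred strain. Per the labels' protocols, dissected forebrains were pooled, with 36 pieces per ChIP library, fixed in 1% formaldehyde and sonicated with 12 pulses of 30 seconds. One library was made with an antibody against trimethylated lysine 4 of histone H3 (H3K4me3, 10 microlitres) and another with an antibody against trimethylated lysine 36 (H3K36me3, 15 microlitres). Each had an input library, made without immunoprecipitation, which the protocol gives as 0.5% input for H3K4me3. The H3K4me3 ChIP DNA and its input were amplified for 8 cycles by whole-genome amplification (WGA) with a primer that carries a BpmI restriction site, and then digested with BpmI. The H3K36me3 ChIP and its input were not amplified, per the labels. Each of the 4 groups therefore held 1 library, and the mark was confounded with the amplification. Tests on tags compared libraries, not conditions, and no spread between replicates could be measured.

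The authors deposited 1 list per library in which each line is a placed tag, with its chromosome, position and strand sign. The positions are in the mouse build mm8, per the submitters' processing notes. The aligner, its settings and the read length are not given in the sources used here. The tags are uniquely placed, per the names of the deposited lists. The lists hold no normalised values, and every count below was made from them. In 3 lists no position and sign occurred more than once, so repeated tags had been collapsed before deposit. The deposited list of the H3K4me3 input kept repeats, with up to 1380 copies of a tag, and consisted of 2 sorted lists joined end to end. Keeping 1 tag per chromosome, position and sign removed 27.5% of its 3464484 nuclear tags. This step made the H3K4me3 input comparable with the other lists, but it limits the height that a place with many true copies can reach.

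The tags used numbered 7606197 for the H3K4me3 ChIP, 2513019 for its input, 10466543 for the H3K36me3 ChIP and 23110768 for its input. The share of plus signs was close to 50.0% in all 4. Mitochondrial tags were left out of all region tests. The 2 parts of the H3K4me3 input shared 318964 positions, and set against each other with the tests below they gave 0 called bins among 7448 tested bins of 1 kb.

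Tags were shifted by 75 bp in the direction of their sign and counted in bins of 1 kb for H3K4me3 and 5 kb for H3K36me3. ChIP and input counts of a bin were compared with a one-sided exact binomial test, in which the expected share came from the library totals. Bins with at least 10 tags in ChIP plus input were tested, and p-values were adjusted by the Benjamini-Hochberg method. A bin was called at an adjusted p under 0.05 with a ratio of ChIP to scaled input, pseudocount 1, of at least 2 for H3K4me3 or 1.5 for H3K36me3. Called bins with a gap of at most 1 bin were merged into regions. The same test with ChIP and input exchanged gave a number of bins beside each real one. That number reflects the unevenness and the depth of the libraries and also the scaling of the input. Ratios of single regions have exact Clopper-Pearson 95% intervals and omit the pseudocount, shares have exact binomial 95% intervals, and the ratios beside region edges and along regions have 95% intervals from 1000 bootstrap draws of regions. Other ratios pooled over regions are given without an interval. All intervals cover counting error, or the spread between regions, in these libraries only.

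The covered genome was taken as the 10 kb bins with at least 1 tag of the unamplified input, 2522.92 Mb. H3K4me3 regions were set against 100 random placements on their own chromosomes among 1 kb bins with a tag of that input. The placements were not matched further, for example on input depth, which limits every comparison with random placement below. The H3K36me3 flanks of an H3K4me3 region were the stretches from 1 to 11 kb beyond each edge, tested like the bins with a ratio of at least 1.5. Flank classes, H3K36me3 inside H3K4me3 regions, the side and position analyses and their alternatives were chosen after the data were seen. The region tests, overlap, input comparison and breadth were fixed before the data were examined. The inputs were thinned to the size of the smaller and compared in autosomal bins with a tag of the full unamplified input, with 1000 bootstrap draws of chromosomes. Background scaling, an alternative, took the input scale from the 10 kb bins at or below the median of ChIP plus input tags.

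The region test was tested on simulated tags that followed the unevenness of the unamplified input and the real depths, with 50 changed bins per fold size. Among 2630741 bins of 1 kb at the H3K4me3 depth, 2% of bins raised 4-fold, 14% raised 8-fold, 68% raised 16-fold and 90% raised 32-fold were called, with 0 false calls. The 2513019 tags of the H3K4me3 input, 0.996 per covered kb, thus limited H3K4me3 calls to high enrichment, and no called bin held fewer than 20 ChIP tags. Among 526173 bins of 5 kb at the H3K36me3 depth, 6% of bins raised 1.5-fold, 20% raised 2-fold, 96% raised 4-fold and all raised 8-fold were called, with 3 false calls. These simulations changed few bins, so scaling by library totals held in them, and the bins with the fewest tags were left unchanged. In the real H3K36me3 libraries the ratio of all tags outside regions was 0.322. The simulated shares therefore do not give the power for enrichment over that background. Apart from the changed bins, simulated ChIP and input followed the same unevenness, so few false calls were built in. The counts of false calls do not hold for the real libraries.

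Gene names, promoters and gene bodies were not used here. The annotation at hand was of another mouse build, and coordinates were not converted, so the planned tests at promoters, over gene bodies and in gene lists were not run. By the rule fixed for that case, the text names the 10 regions of each mark with the most ChIP tags over scaled input, the 5 widest of each mark and the 5 highest 1 kb bins of each input, by mm8 coordinates. Alternatives varied the collapse of repeats, the scaling of the input, thresholds, the input used, the shift, the tag minimum, the depth, the bin size, the gap and the overlap distance. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.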

Results

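The series profiled 2 histone marks in the forebrain of mouse embryos at day 11.5, each beside its own input. H3K4me3 is a mark of active and poised promoters, and H3K36me3 is laid down over the bodies of transcribed genes. Depth ranged from 2513019 used tags in the H3K4me3 input to 23110768 in the H3K36me3 input, with 1 library per group. All coordinates are in the build mm8.

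The first comparison asked where the H3K4me3 ChIP exceeded its input. H3K4me3 formed 7781 short regions that together covered 12.7 Mb, or 0.502% of the covered genome. The median region was 1 kb wide, and 4298 regions consisted of a single bin. Regions held 8.11% of ChIP tags but 0.403% of input tags, and the median ratio of ChIP to scaled input was 21.9 (interquartile range 10.7 to 37.0). These ratios rest on a median of 1 input tag per region and depend on the pseudocount. In all regions together the ChIP stood at 16.1 times its genome mean and the unamplified input at 2.76 times. Of 168918 tested bins 12382 were called, against 16 with ChIP and input exchanged. The input held 0.996 tags per covered kb, so few bins could be called in exchange, and the 16 say little about false calls. With the input's repeats kept, set against collapsed ChIP tags, 15243 bins were called and 37304 in exchange. In 3195 regions the input held no tag. Against the deeper unamplified input 31981 regions were called, and 51580 bins were then called in exchange, so the number of regions depends on the input used.

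The region with the most tags over input was also the widest H3K4me3 region. It spanned 27 kb on chromosome 13 (84188001 to 84215000) and held 1931 ChIP tags against 22 input tags, a ratio of 29.0 (19.1 to 46.4). The next in width lay on chromosome 12 (50258001 to 50272000, ratio 26.4, 12.7 to 65.9) and measured 14 kb. Regions of 12 kb lay on chromosome 7 (79372001 to 79384000, ratio 12.8, 8.52 to 20.02) and chromosome 13 (78656001 to 78668000, ratio 23.5, 11.8 to 54.6). A region of 11 kb lay on chromosome 2 (115752001 to 115763000, ratio 12.2, 7.59 to 21.2). The other regions named for their tags over input were narrower. They lay on chromosome 10 (36824001 to 36831000, ratio 78.9, 26.9 to 383), chromosome 18 (55111001 to 55119000, ratio 36.8, 16.8 to 100.7), chromosome 9 (41331001 to 41337000, ratio 16.8, 9.74 to 31.7), chromosome 13 (28956001 to 28962000, ratio 63.4, 21.6 to 308.5) and chromosome 5 (143079001 to 143088000, ratio 27.4, 13.2 to 68.5). The same rule named 2 regions of chromosome 2. The region 77746001 to 77748000 held 597 ChIP tags against 2 input tags (ratio 98.6, 27.2 to 816). The region 98463001 to 98468000 held 1092 against 104 (ratio 3.47, 2.83 to 4.28), but the deposited repeats of the input, if kept, raised its input to 1603 tags and turned the ratio to 0.310 (0.287 to 0.335). The ChIP list had been collapsed before deposit, so that ratio sets uncollapsed input against collapsed ChIP tags. Heights depended on the input: against the unamplified input, with pseudocount 1, the ratio of the region at 77746001 was 7.48 (6.50 to 8.82), those at 36824001 and 28956001 were 18.8 and 12.9, and the 12 named regions ranged from 2.46 to 36.5.

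The second comparison asked where the H3K36me3 ChIP exceeded its input. H3K36me3 formed 11107 long regions that covered 285 Mb, or 11.3% of the covered genome. Their median width was 15 kb (interquartile range 5 to 35 kb), and 284 regions were at least 100 kb wide. Regions held 73.3% of ChIP tags and 17.1% of input tags, and the median ratio was 3.28 (interquartile range 2.32 to 4.78). Of 466177 tested bins 53157 were called. The exchanged test called 309410 bins, and outside H3K36me3 regions the ratio of all tags was 0.322. Scaling the input on background bins called 112368 bins, 423 in exchange, in 20678 regions that covered 601 Mb.

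The H3K36me3 region with the most tags over input lay on chromosome 5 (142955001 to 143085000) and held 10285 ChIP tags against 2729 input tags, a ratio of 8.32 (7.98 to 8.68). It overlapped the named H3K4me3 region of chromosome 5 at its end of higher coordinate. The highest ratio among the 10 leading regions, 9.15 (8.72 to 9.59), belonged to another region of chromosome 5 (145025001 to 145120000). Chromosome 4 held 3 of the 10 leading regions (147295001 to 147470000, ratio 6.29; 137265001 to 137520000, ratio 5.28; 138660001 to 138765000, ratio 7.41). The others lay on chromosome 2 (77690001 to 77745000, ratio 4.68), chromosome 12 (76795001 to 77035000, ratio 5.95), chromosome 5 (102070001 to 102295000, ratio 5.92), chromosome 17 (55985001 to 56105000, ratio 5.31) and chromosome 3 (88770001 to 89030000, ratio 7.60). The chromosome 3 region was the widest at 260 kb. The last regions entered by width alone, on chromosome 13 (81850001 to 82095000, 245 kb, ratio 3.49) and chromosome 4 (107960001 to 108190000, 230 kb, ratio 4.55). These heights depended on the scaling: with background bins the leading region stood at 34.5 (33.2 to 36.1), and the 12 named H3K36me3 regions ranged from 14.4 to 37.9.

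The third comparison set the marks against each other. Of the H3K4me3 regions, 31.5% (30.4 to 32.5) overlapped an H3K36me3 region, against 13.4% of randomly placed regions (range of 100 placements 12.5 to 14.3). Within 5 kb the share was 71.7% (70.7 to 72.7), against 18.1% at random (17.1 to 19.05). Both shares exceeded those of random placements, which were not matched on input depth. Overlap here means contact with merged 5 kb bins, not H3K36me3 on the H3K4me3 region itself. Tested on the tags inside each H3K4me3 region, H3K36me3 was called at 227 regions, or 2.92% (2.55 to 3.32), though narrow regions hold few tags. The overlap itself depended on the scaling, and with background scaling 64.1% of H3K4me3 regions overlapped an H3K36me3 region (27.5% at random). Inside H3K4me3 regions the H3K36me3 ChIP stood at 1.25 times its genome mean, while the unamplified input stood at 2.76 times its own. The WGA input, which took part in choosing these regions, stood at 0.802 times. Whether H3K36me3 lay below or above input there thus depended on the input used.

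H3K36me3 most often began on 1 side of an H3K4me3 region. It was called in 1 flank of 4588 regions, or 59.0% (57.9 to 60.1), against 9.93% of random placements and 49.9% if the flanks of these regions were called independently. Both flanks were called at 1466 regions (18.8%, 18.0 to 19.7; 8.34% at random) and neither flank at 1727 (22.2%, 21.3 to 23.1; 81.7% at random). Around regions of the 1-sided class, which the calls in these flanks define, H3K36me3 tags stood at 7.11 times the genome mean from 1 to 11 kb on the called side and 0.536 times on the other. Of the 12 named H3K4me3 regions 10 had H3K36me3 in exactly 1 flank, but with background scaling 3 did, 8 had it in both and 1 in neither. At the chromosome 9 region the ratios were 1.04 (0.721 to 1.48) in the flank of lower coordinate and 10.9 (8.49 to 14.1) in the other. At the chromosome 5 region they were 8.70 (7.34 to 10.4) and 0.845 (0.620 to 1.14). The classes depended on the scaling. With background bins, regions with neither flank called fell to 4.10%, against 63.3% of 20 random placements, 41.5% had both flanks called, and the low flanks of the chromosome 9 and chromosome 5 regions were called too, at 4.32 and 3.51.

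**Figure D1:**
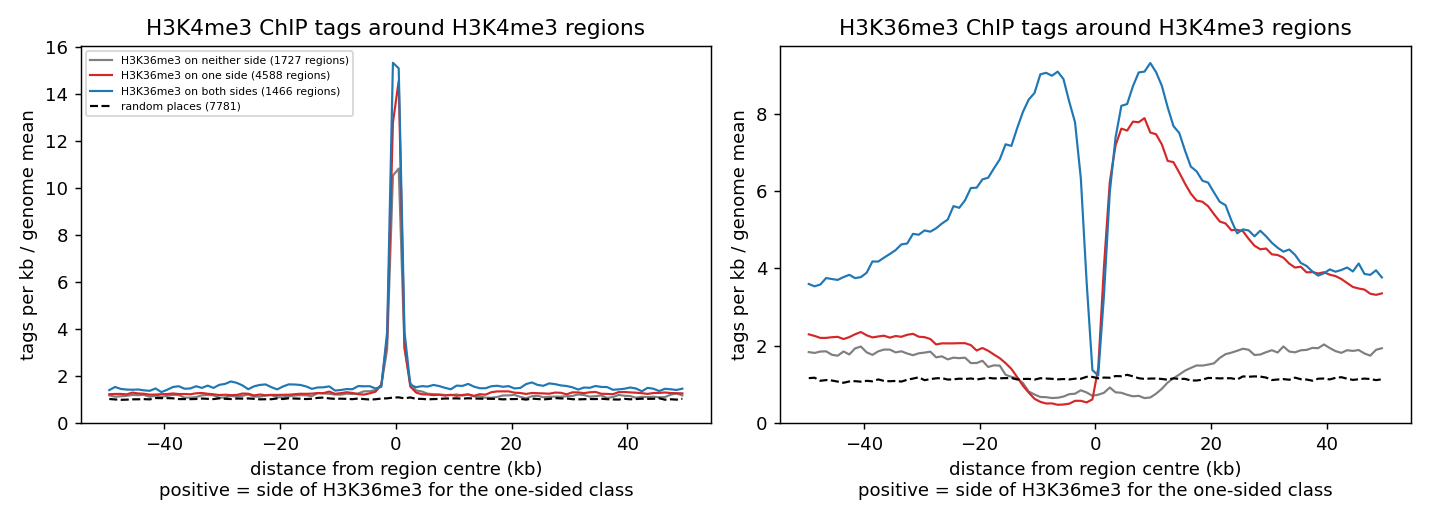
Mean tags per kb, divided by the genome mean, of the H3K4me3 ChIP (left) and the H3K36me3 ChIP (right) against distance from the centre of H3K4me3 regions in kb, for the 3 flank classes (solid lines; 1727, 4588 and 1466 regions) and for 7781 random places (dashed). The 1-sided class, defined by the calls in these flanks, is turned so that its H3K36me3 lies at positive distances; there it averages 7.11 from 1 to 11 kb, against 0.536 at the mirrored negative distances. In the class with both flanks called H3K36me3 dips at the centre, to 1.30 within 1 kb.

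Relative to its own input, scaled by library totals, H3K36me3 was low inside short H3K4me3 regions and high inside many of the broadest. That input stood at 2.76 times its genome mean in all H3K4me3 regions together, which lowers the ratios. The WGA input, which took part in choosing these regions, stood there at 0.802 times. Among 4298 regions of 1 kb, 48 (1.12%, 0.825 to 1.48) had H3K36me3 called inside, and the pooled ratio was 0.234. Among 2469 regions of 2 kb the share was 2.96% (2.32 to 3.70), and among 943 regions of 3 to 4 kb it was 7.95% (6.31 to 9.87). Among the 71 regions of at least 5 kb it was 43.7% (31.9 to 56.0), with a pooled ratio of 2.83 and a median of 1.41. The median was 0.182 in regions of 1 kb, 0.175 in those of 2 kb and 0.234 in those of 3 to 4 kb. With this scaling the ratio of all tags outside H3K36me3 regions was itself 0.322. The low values in short regions therefore do not show depletion below background. All 5 of the widest H3K4me3 regions carried H3K36me3 inside. The chromosome 13 region of 27 kb had a ratio of 7.21 (6.33 to 8.24) inside, yet 0.457 (0.223 to 0.860) and 0.487 (0.270 to 0.832) in its flanks. The chromosome 7 region of 12 kb had 9.15 (8.17 to 10.3) inside, 4.72 (4.03 to 5.55) in the flank of higher coordinate and 0.198 (0.111 to 0.331) in the other. Wider regions hold more tags and pass the test more easily. With background scaling the shares were 70.4% at 5 kb or more and 4.89% at 1 kb, and the flanks of the 27 kb region stood at 1.90, not called, and 2.03, called.

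**Figure D2:**
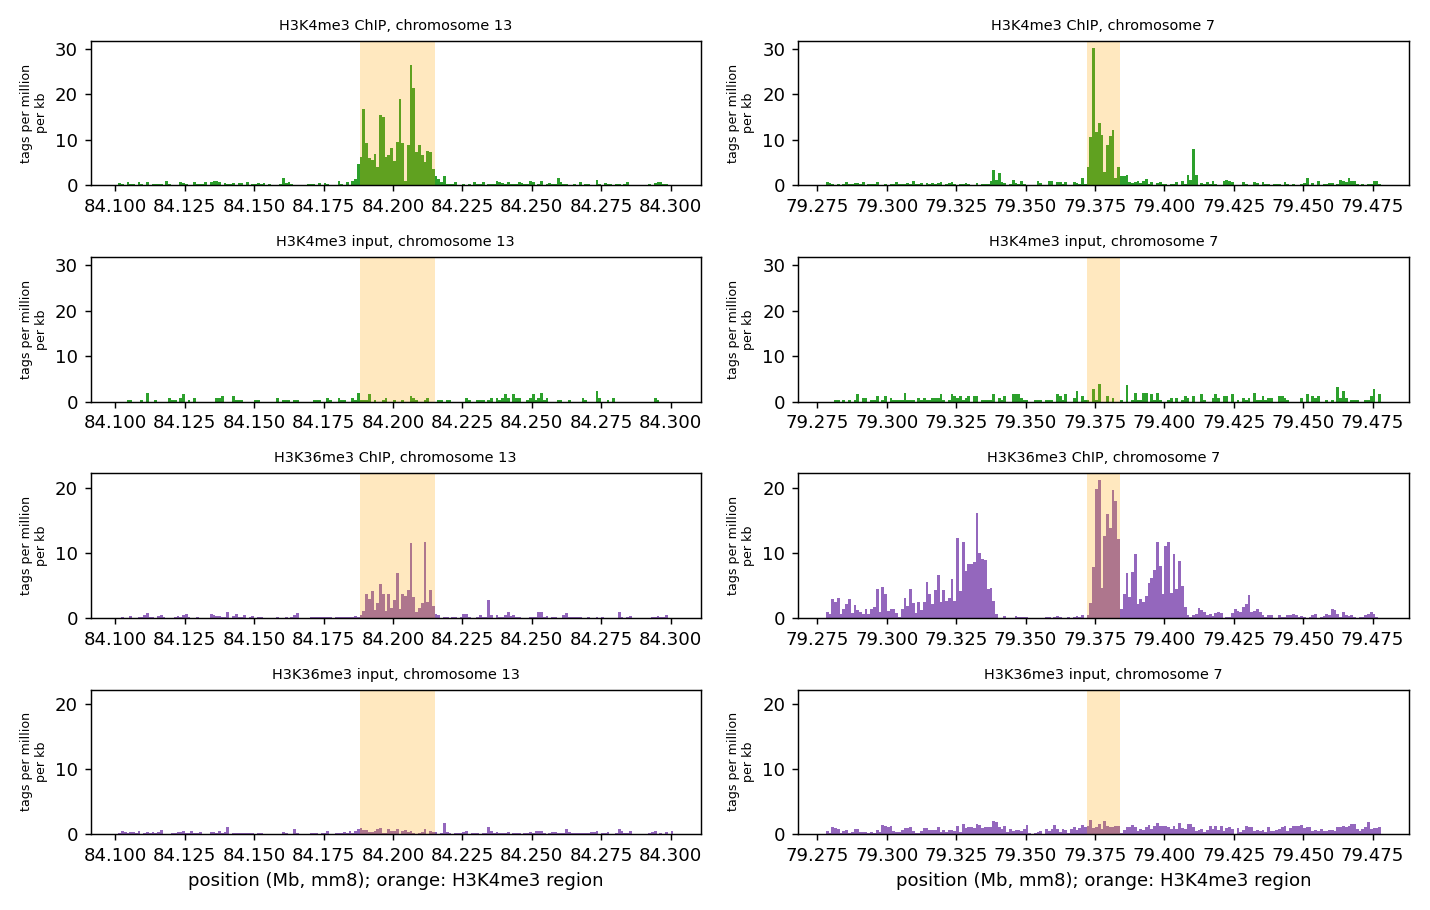
Tags per kb, scaled to counts per library size (CPM), around the widest H3K4me3 region (left column, chromosome 13) and around the region with the second most tags over input (right column, chromosome 7), for the 4 libraries from top to bottom, with the named H3K4me3 region shaded in orange. H3K36me3 fills the shaded region of chromosome 13 (ratio 7.21) and is lower in its flanks (0.457 and 0.487). On chromosome 7 it goes on into the flank of higher coordinate (4.72) and is low in the other (0.198). Ratios are to input scaled by library totals, for which all tags outside H3K36me3 regions gave 0.322.

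Broad H3K4me3 regions held tags about in proportion to their width. The plan named the broadest 5% of regions. Widths come in whole kb, so the cut fell at 3 kb, and the 1014 regions of at least that width made up 13.0% of regions, 27.1% of the total width of regions and 28.5% of H3K4me3 tags in regions, with a median of 47 tags per kb against 42 in the rest. They had H3K36me3 in neither flank less often than the rest, 15.0% (12.8 to 17.3) against 23.3% (22.3 to 24.3). The regions of 1 kb carried that difference, at 27.3% (25.9 to 28.6), while those of 2 kb stood at 16.3% (14.9 to 17.8). Both flanks were called at 26.2% of the regions of at least 3 kb and at 17.7% of the rest. Of the 71 regions of at least 5 kb, 16.9% (9.05 to 27.7) had both flanks called and 19.7% (11.2 to 30.9) neither, intervals too wide to set them apart from either group.

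Seen from the H3K36me3 regions, 40.1% (39.2 to 41.0) had H3K4me3 within 5 kb, against 11.6% with randomly placed H3K4me3 regions (10.99 to 12.2). Of regions of 5 kb 15.5% (14.3 to 16.8) had it, against 5.37% at random, and of regions over 100 kb 71.8% (65.7 to 77.5), against 38.0%. H3K36me3 regions with H3K4me3 nearby had a median ratio of 4.61, against 2.65 for those without, but they were also wider (median 25 against 10 kb). Within width classes the medians were 2.81 against 2.26 at 5 kb, 4.59 against 2.71 up to 20 kb, 4.80 against 3.31 up to 50 kb, 4.80 against 3.83 up to 100 kb and 5.01 against 4.20 above. Of 2225 H3K36me3 regions of at least 20 kb with exactly 1 H3K4me3 region, 1888 had it within 5 kb of an end, or 84.9% (83.3 to 86.3), where even placement along the region gives 43.6%. The end of lower coordinate was used 939 times and that of higher coordinate 949 times.

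Along these 1888 regions, H3K36me3 was low at both ends and nearly level between them. From the H3K4me3 end, in 10 equal parts, the ratio was 3.76 (3.62 to 3.89) in the first, 5.16 (5.002 to 5.33) in the second, 5.53 (5.35 to 5.71) in the eighth and 3.58 (3.46 to 3.70) in the last. The ratio of the 5 far parts to the 5 near parts was 1.01 (0.988 to 1.03). Against the WGA input it was 1.11 (1.07 to 1.14), so whether H3K36me3 rose away from H3K4me3 depended on the input. Tags of the ChIP alone rose from 28.9 per kb in the second part to 36.6 in the eighth. H3K4me3 stood at a ratio of 2.25 (2.10 to 2.40) in the first part and 0.918 (0.883 to 0.957) in the second. The ends of H3K36me3 regions are borders of called 5 kb bins, so the end parts can hold stretches without the mark. Among the 558 of these regions of at least 50 kb, the low ends were less marked. There the H3K36me3 ratio against its own input was 4.30 in the first part, 5.01 in the second and 4.04 in the last.

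**Figure D3:**
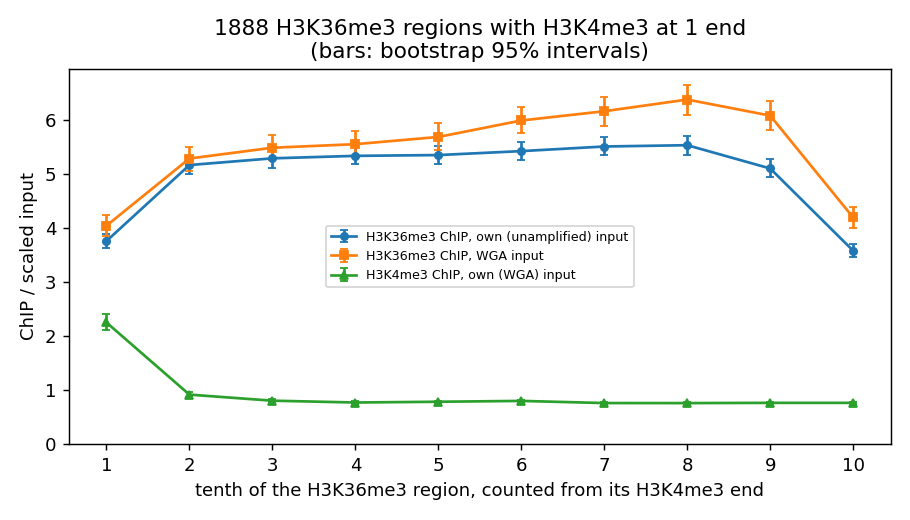
Ratio of ChIP to scaled input in 10 equal parts of 1888 H3K36me3 regions, counted from the end with H3K4me3, with bootstrap 95% intervals. H3K36me3 against its own input (circles) runs from 3.76 to 5.53 and back to 3.58, against the WGA input (squares) it peaks at 6.38, and H3K4me3 (triangles) falls from 2.25 to 0.918 after the first part.

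H3K4me3 tags beyond the region edges were slightly fewer on the H3K36me3 side in the second kb, and no difference was shown in the kb on either side of it. In the first kb beyond the edges of the 4588 regions with 1 called flank, the ratio of H3K4me3 tags on the H3K36me3 side to those on the other was 0.974 (0.947 to 1.00). In the second kb it was 0.903 (0.872 to 0.937) and in the third 0.965 (0.916 to 1.01). The WGA input leaned the other way in the first kb, 1.18 (1.12 to 1.23). The unamplified input was lower on the H3K36me3 side there, 0.775 (0.754 to 0.797).

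Both marks were densest on chromosome 11 and sparsest on the X chromosome. Chromosome 11 held 5.20 H3K4me3 regions per covered Mb (exact Poisson 95% interval 4.80 to 5.63) and 6.23 H3K36me3 regions (5.78 to 6.69). The autosomes together held 3.17 (3.10 to 3.24) and 4.52 (4.43 to 4.60). The X chromosome held 1.73 (1.53 to 1.95) and 2.65 (2.39 to 2.92), and H3K36me3 regions covered 4.90% of it against 11.7% of the autosomes. Input depth on X was 0.513 (WGA) and 0.398 (unamplified) of the autosomal mean, which lowers the power to call regions there. On chromosome 11 it was 1.19 (WGA) and 1.31 (unamplified) times that mean, which raises the power. Relative to input, all H3K4me3 tags on X stood at 1.21 times and all H3K36me3 tags at 0.607 times the autosomal level. Of H3K4me3 ChIP tags in the genome 8.11% lay in regions, so the value of 1.21 does not show a raised mark on X. H3K4me3 regions covered 0.254% of X against 0.518% of the autosomes.

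**Figure D4:**
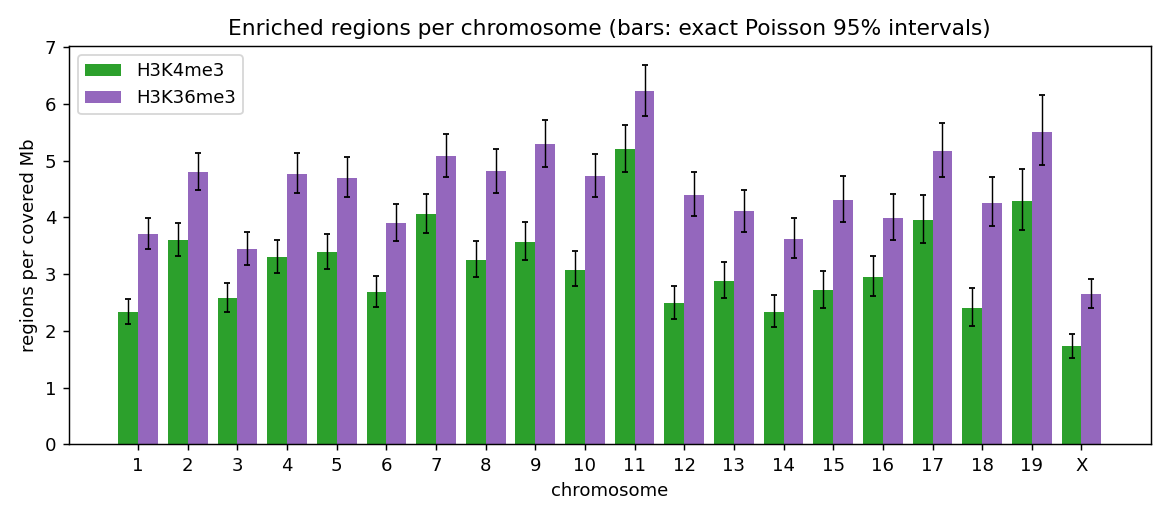
Regions per covered Mb on each chromosome for H3K4me3 (green) and H3K36me3 (purple), with exact Poisson 95% intervals. Chromosome 11 has the most of both (5.20 and 6.23) and X the fewest (1.73 and 2.65).

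The last comparison set the amplified input against the unamplified input on the autosomes, after both were thinned to 2513019 tags. In 1 kb bins the WGA input was about as uneven as the other, with a variance over mean of 1.85 against 1.79, a ratio of 1.03 (0.969 to 1.09, bootstrap over chromosomes). In 10 kb bins it was more even, 3.65 against 6.63, a ratio of 0.550 (0.490 to 0.609). With repeats kept in the WGA input, at 3464484 tags each, it was more uneven in 1 kb bins, 5.05 against 2.10. The unamplified list had been collapsed before deposit, so these values set a list with repeats against one without. Across bins, which are not independent replicates, the inputs correlated weakly at 1 kb (Spearman 0.171) and more at 10 kb (0.619). With 1 library each, amplification and library cannot be told apart.

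The highest bins of the WGA input lay on chromosome 2 (98467001 to 98468000 with 43 tags, 98463001 to 98464000 with 39, 77751001 to 77752000 with 36 and 77688001 to 77689000 with 34) and chromosome 11 (3077001 to 3078000 with 35), against a mean of 0.996 per kb. All 5 highest bins of the unamplified input lay within 6 kb of chromosome 17 (39451001 to 39457000), with 1004 to 1701 tags each against a mean of 9.16. Over that stretch the unamplified input stood at 139 times its genome mean and the H3K36me3 ChIP at 135 times. The H3K4me3 ChIP stood there at 5.47 times and the WGA input at 5.02 times.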

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

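Mitochondrial tags, which no comparison used, appeared in the H3K4me3 ChIP above the level of its input. After collapse they numbered 511, or 67.2 CPM (counts scaled to library size; exact 95% interval 61.5 to 73.3), against 62 in the WGA input, or 24.7 CPM (18.9 to 31.6). The ratio was 2.72 (Fisher's exact test, two-sided, p = 3.79e-17), which compares 2 libraries and not conditions. The unamplified input held 97 mitochondrial positions, or 4.20 CPM (3.40 to 5.12), and the list of the H3K36me3 ChIP held 0. Whether mitochondrial tags were left out of that list before deposit is not given in the sources used here. This comparison was chosen after the counts were seen, and no explanation was tested.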

How the results depend on the processing

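Alternatives for flank classes, H3K36me3 inside broad regions, sides, positions, regions of high input, exchanged input signs and overlap after background scaling were chosen after seeing the data. Planned tests at promoters, over gene bodies and by gene class were not run, for lack of an annotation of the build. H3K4me3 regions numbered 4607 at adjusted p under 0.001 and 31981 against the unamplified input, and stayed within 1.5 times of 7781 elsewhere, with 7791 after exchanging the input's signs. H3K36me3 regions numbered 20678 with background scaling, 20231 in 2 kb bins and 7309 in 10 kb bins; keeping all tags moved nothing there, since those lists were already collapsed. Overlap of the marks was 71.7% within 5 kb and 64.1% after background scaling (27.5% at random). The unevenness ratio of the inputs was 2.41 with all tags, where only the WGA input kept repeats, and 0.550 in 10 kb bins. Regions of at least 3 kb made up 9.54% without gaps and 14.4% with gaps of 3 bins. The share with H3K36me3 in neither flank, 22.2%, became 27.4% with flanks to 6 kb, 19.8% to 21 kb, 29.8% at a ratio of 2, 29.2% with the WGA input, 4.10% with background scaling and 31.1% after thinning. The 1-flank share, 59.0%, became 55.8% with flanks to 21 kb, 55.0% at a ratio of 2, 53.3% both with the WGA input and after thinning, and 54.4% with background scaling. H3K36me3 inside regions of at least 5 kb, 43.7%, became 56.3% with the WGA input, 70.4% with background scaling, 35.2% after thinning and 45.3% without regions of high input. H3K4me3 on the H3K36me3 side passed the threshold in the second kb (0.903), and H3K36me3 away from H3K4me3 did so against the WGA input (1.11). The 24 named regions were chosen from these data for tags over input or width. Most of their ratios lay far above the thresholds, so agreement between settings says little about other regions. Among their comparisons, 24, of H3K36me3 with all tags or background scaling, could not change. Of the 96 that could, 95 kept their direction and side of the threshold. The exception was the H3K4me3 region at 98463001 on chromosome 2, reversed to 0.310 by the input's repeats, which were set against collapsed ChIP tags. Other causes were not tested. The depth of the H3K4me3 input limits which H3K4me3 regions can be seen.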

Other observations

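Of the tests below, 2 were fixed before their result was seen (too few flank tags, and false H3K4me3 calls through the shallow input), and the others were chosen after it. No biological explanation was tested.

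Tags of opposite sign paired at a fixed spacing in both amplified libraries. In the H3K4me3 ChIP the spacing was -3 bp, 20.02 times the median over spacings and 10.6% of plus positions, and in its input it was 37 bp, 215 times the median and 21.5% of plus positions. In the unamplified libraries no spacing within 100 bp exceeded 1.40 times the median, as the WGA preparation with its BpmI digestion would predict if many tags start at fixed cut sites, though the mark differs too. A different convention for minus positions alone is argued against, since plus positions of the input lay at -37 bp from those of the ChIP, where it needs 0. Positions of opposite sign matched 1.22 times as often as those of the same sign, at an offset of 0 bp for plus in the ChIP, so the signs of the H3K4me3 input may be exchanged in the list, with positions given at the lowest coordinate of a 35 bp read.

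H3K4me3 regions with H3K36me3 in neither flank made up 1727 of 7781. False H3K4me3 calls cannot be told apart from real ones: 91.0% (89.5 to 92.3) were also enriched over the unamplified input, against 96.3% of the other H3K4me3 regions. That interval spans the bound set beforehand, and the test reuses the ChIP tags that selected the regions. Too few flank tags cannot be told apart as a cause either, since the flank intervals of 35.0% of these regions reached a ratio of 1.5, between the bounds set beforehand. The class depended on the scaling of the H3K36me3 input: 18.5% (16.7 to 20.4) kept neither flank called with background scaling. That scaling applies 1 factor to all flanks, and it left 77.5% of random places without a called flank in that class. Which scaling is right was not tested, so scaling by library totals as a cause cannot be told apart either.

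The H3K36me3 region with the second most tags over input (chromosome 2, 77690001 to 77745000) ended 1 kb before an H3K4me3 region with 597 ChIP tags against 2. Its inputs stood at 6.21 times (WGA) and 10.3 times (unamplified) their genome means, which suggests more copies of the sequence than the reference holds. Copies lift ChIP and input alike. The H3K36me3 ratio to the WGA input, which took no part in choosing the region, was 7.78 (6.98 to 8.69). More copies as the whole cause stay open, since the ChIP tags of that ratio are those that ranked the region. Collapse also limits the WGA input, which held 340 tags there, or 836 with repeats kept. In the flank beyond the H3K4me3 region, 405 input tags stood beside 33 H3K36me3 tags, a ratio of 0.180 (0.122 to 0.257). Enrichment by the antibody was not tested apart from the choice of the region and stays open.

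At the H3K4me3 region of chromosome 2 from 98463001 to 98468000, the collapsed WGA input stood at 20.9 times its genome mean and the same input with repeats at 233 times. At the stretch of chromosome 17 from 39451001 to 39457000, the WGA input with repeats stood at 8.74 times its mean, against 139 times in the unamplified input. Regions called on the Y chromosome numbered 4 for H3K4me3 and 8 for H3K36me3.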
